A study of Xenopus tropicalis with 8 samples.

How the data were processed

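RNA from testis tissue of juvenile male Xenopus (Silurana) tropicalis was measured on 8 Agilent arrays in one colour (Cy3), 4 from tissue kept without finasteride and 4 from tissue kept with 5 µM finasteride. Per the labels' protocols, the RNA was extracted with TRIzol. The design text gives 8 samples per arm, and 4 arrays per arm were analysed here. The labels do not say whether the arrays hold separate animals or pools, so the p-values measure only the spread between these samples, which may be technical.

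Each array's spot intensity was deposited as scanner output made with Agilent Feature Extraction 10.7.1.1, per the file headers, which also name the JGI 4.1 genome build. How that software corrected the background of the processed intensity is not given in the sources used here. The deposited files also carry flags for spots that were outliers, saturated or well above background, per the file headers. The authors' deposited table of the whole series holds log2 values. Set against each array's own processed intensity, they matched a quantile normalization of log2 intensity over all spots, with a median of 7.25 on every array and the direction of the intensity. No processing step of that table is stated in the sources used here.

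From these files, log2 processed intensity was taken per spot, outlier spots and control spots were left out, and the spots of a probe were averaged, at most 2 per probe. Each array's 75th percentile over the probes was subtracted, so that a level of 0 is that percentile. Of 32899 probes, 25652 were tested, those well above background on at least 3 of the 4 arrays of either group. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term), with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05 on the adjusted p. Intervals are 95% confidence intervals of the limma fit. They are not adjusted for the choice of genes, so for genes named for a low p they may overstate the difference. Where a probe was not well above background on any array of a group, the fold is a lower bound as to the dim signal, not as to the spread between arrays. It sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own signal and the lowest signal of any probe well above background on that array.

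The files give an accession per probe and no gene name. The names of 17780 probes hold the word specific and those of 15119 hold xhyb. Among the genes named below, epb41, fgg, n6amt1, tacc1, hoxa13, pgrmc2, fosl1, orc1 and cyp2a6.1 were read from xhyb probes. Whether an xhyb probe reads only its own gene was not tested. Without version numbers, 5891 probes matched a transcript of the RefSeq gene table of assembly UCB_Xtro_10.0, which was used for names only because its build differs from that of the arrays. Of these, 1019 had only a provisional locus name and 4872 had a gene symbol. The 17595 probes designed on other accessions matched none. A gene was read from its probe of highest mean signal, which left 3845 named genes tested. The steroid 5-reductase list held the genes of steroid 5-alpha-reductase, the enzyme finasteride inhibits, and other reductase genes. No gene of that list could be named on a probe, so these genes and the alternatives listed for them were not analysed here.

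The tests, the alternatives, the rule for named genes and 31 gene lists were fixed before the data were examined. Genes were named if they passed the threshold with no overlap between groups, up to 14 per direction. Where fewer passed, genes with no overlap and the lowest unadjusted p filled the places and are given as values, not as changes. Up to 4 members with the lowest p were named from a list. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. That test used 4478 genes with a value on every array, provisional locus names included. List members were matched by symbol, tandem copy or older symbol, the last alone for 3 members (hes5.1, sox17b.2 and mrpl24). Members were also counted at a threshold adjusted over the list alone. That adjustment was made for each list separately and not over the lists, so some such passes may arise by chance.

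The steps were tested on simulated arrays with the means and spread of the real probes. Of probes changed 1.5-fold, 2.4% were recovered, against 39.6% at 2-fold, 82.8% at 4-fold and 94.8% at 8-fold, with 25596 probes simulated and 3.17% of the calls false. Each run held 50 changed probes at every fold, and both groups were given the same spread. The adjustment is stricter where fewer probes change, and the real finasteride arrays spread more widely than controls. These shares may therefore be too high for the real data. A list of 14 genes shifted by 0.25 on the log2 scale was called in 85% of 20 runs with 4478 genes simulated. The simulated genes varied independently, while the estimated correlation within a real list was up to 0.36 (proteasome). Shifted lists whose genes vary together, or with fewer members, were not simulated, so that share may be too high for the real lists.

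Alternatives were another background correction (normexp with an offset of 50), quantile normalization, median centring, the deposited log2 table, other filters on dim probes, slide and replicate number as blocks, each slide alone, another variance model, array weights, averaging over probes, other thresholds and leaving out each array. The normexp alternative was planned on mean signals. It was run on median signals, because the mean signal column is not among the columns of the files used here, so it differs in the signal as well as in the background correction and the effects of these were not separated. The arrays lay on 2 slides, each with 2 arrays of each group, and every array was scanned on the same day.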

Results

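Testis tissue of juvenile male Xenopus (Silurana) tropicalis, a frog, was kept for 6 h at 26 °C in culture medium with 5 µM finasteride, an inhibitor of steroid 5-alpha-reductase, or without it (0 µM). Transcript levels were read on 4 arrays per group. The 75th percentile of processed intensity ran from 719 on control 1 to 1798 on finasteride 2, and no probe was saturated. Probes well above background made up 75.4% ± 1.70 of all probes on control arrays (SD, n = 4) and 79.4% ± 6.98 on finasteride arrays (SD, n = 4), with 70.5% on finasteride 4 and 86.9% on finasteride 3. The number of arrays limits the precision: the median half-width of the 95% interval of a log2 fold change was 0.49.

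The arrays were compared as wholes before genes were. Correlations over the tested probes, which are not independent replicates, ran from 0.968 to 0.987 within controls, from 0.965 to 0.976 within finasteride and from 0.961 to 0.984 between the groups. The first principal component held 30.4% of the variance and did not separate the groups (exact permutation p = 0.343, two-sided, n = 4 each, smallest possible 0.0286). It placed control 2 and control 4 at one end and finasteride 1 at the other. No probe differed between the 2 slides in limma with group as a covariate (0 at the threshold, 491 at an unadjusted p under 0.05).

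**Figure D1:**
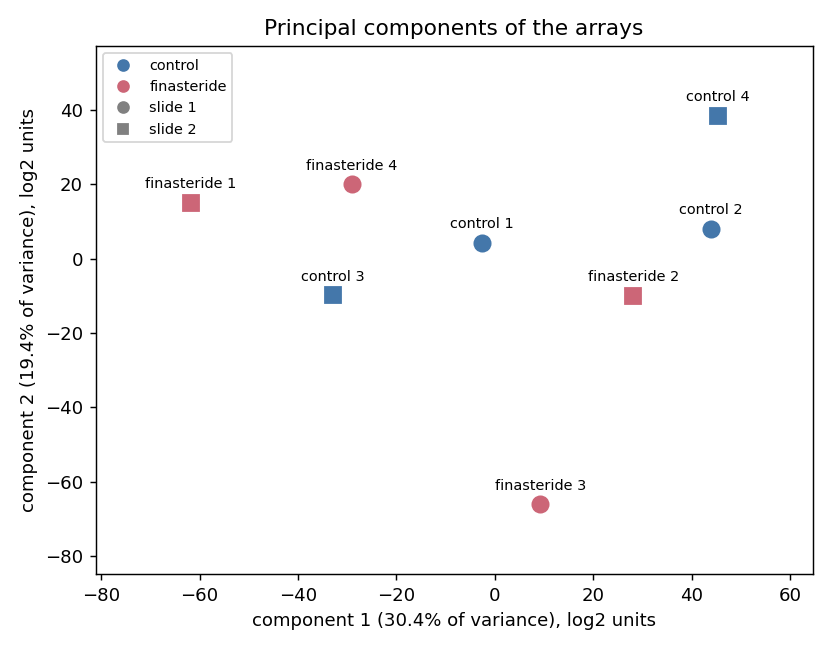
First principal component (horizontal) against the second (vertical), in log2 units, 1 point per array, coloured by group and shaped by slide. Control 3 lies among the finasteride arrays on the first component, and control 2, control 4 and finasteride 2 lie on the right.

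Which genes differed after 6 h with finasteride was the question of the design. No gene passed the threshold in either direction. The named gene with the lowest p on the higher side was micu2, a regulator of the mitochondrial calcium uniporter, with a log2 fold change of 1.18 (95% interval 0.80 to 1.55, limma adjusted p = 0.266), and on the lower side gpr162, an orphan receptor, with -2.57 (-3.80 to -1.34, adjusted p = 1.00). The level of gpr162 was 1.05 ± 0.25 on control arrays and -1.52 ± 1.33 on finasteride arrays (SD, n = 4 each). Heat shock protein gene hspa1b, at 6.17 ± 0.36 in controls and 5.15 ± 0.45 with finasteride, had a log2 fold change of -1.01 (-1.60 to -0.43, adjusted p = 1.00), and -0.62 within slide 2. All values of these genes lay on one side of the other group's values, as the rule for naming them required.

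In limma, 0 probes were higher and 0 lower at the threshold among 25652 tested, with a lowest adjusted p of 0.191. At an unadjusted p under 0.05 there were 585 higher and 440 lower, 4.00% of the probes tested, where 5% would be drawn by chance (1282.6 probes). Groups did not overlap for 76 of the 3845 named genes (1.98%) and for 2.08% of all probes, where chance gives 2.86%. The differences of 98.5% of probes were under 2-fold. With slide as a block the counts were 0 and 0, within slide 1 they were 0 and 0, and within slide 2 they were 1 and 0. That 1 probe was c1ql4, noticed after its value was seen, at 5.80 (5.07 to 6.53, adjusted p = 0.0138) within slide 2, -1.27 (adjusted p = 1.00) within slide 1 and 2.27 (adjusted p = 1.00) over all arrays. Counts also moved when an array was left out: 1 higher and 6 lower without control 3, 2 lower without finasteride 1, 2 higher without finasteride 2, and 1 higher and 1 lower without finasteride 4. Without finasteride 4, gpr162 had a log2 fold change of -3.23 (-3.70 to -2.75, adjusted p = 0.00427). Of the 14 probes called in these fits 3 had a gene symbol, c1ql4, gpr162 and crp.3, the last with -2.99 (adjusted p = 0.0279) without control 3 and -2.04 (adjusted p = 1.00) over all arrays. Positions 1 and 3 of a slide held only controls and positions 2 and 4 only finasteride, so position and treatment cannot be told apart.

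The named genes with higher values under finasteride are given as values, since none passed the threshold. The erythrocyte membrane skeleton gene epb41 had a log2 fold change of 1.26 (0.67 to 1.85) and was well above background on 1 control array and 4 finasteride arrays. Its probe, like those of fgg and n6amt1, was named xhyb, so its values may not be specific to the gene. The glycosyltransferase gene poglut2 had 1.24 (0.47 to 2.01), mss51 0.81 (0.30 to 1.32), the keratin gene krt18.2 0.69 (0.23 to 1.16) and prrt1b 0.69 (0.31 to 1.07). The homeobox gene rax2 had 0.58 (0.23 to 0.93), the fibrinogen chain gene fgg 0.58 (0.16 to 0.99), the methyltransferase gene n6amt1 0.55 (0.22 to 0.89) and the amino acid transporter gene slc7a10 0.44 (0.13 to 0.76). With normexp on median signals rax2 stood at 0.94 and slc7a10 at 0.80, within slide 1 poglut2 stood at 0.78, and within slide 2 krt18.2 stood at 0.41. The genes tmprss2.2 (a transmembrane protease), pop5 (a ribonuclease P subunit), cxcl10 (a chemokine) and fev (a transcription factor), were not well above background on any control array and were on 3 finasteride arrays. With the control signal taken at its floor, their finasteride mean was at least 1.71-fold, 1.60-fold, 1.94-fold and 3.44-fold higher, in that order. The bound was 1.55-fold for cxcl10 without finasteride 4 and 2.14-fold for fev without finasteride 2. These bounds allow for dim control signal only, not for the spread between arrays. The log2 fold changes fitted to the signal as read were 1.40 (0.85 to 1.95), 0.70 (0.32 to 1.08), 1.21 (0.42 to 2.00) and 2.11 (0.64 to 3.58), in the same order. The adjusted p was 0.711 for tmprss2.2 and 1.00 for the others in this paragraph.

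The named genes with lower values included the lipase inhibitor gene angptl4, with a log2 fold change of -0.81 (-1.31 to -0.31), and thsd1, with -0.70 (-1.13 to -0.27). The heme oxygenase gene hmox1 had -0.69 (-1.14 to -0.25), tacc1 -0.75 (-1.27 to -0.24), vwc2 -1.01 (-1.67 to -0.34) and monoamine oxidase gene maob -0.57 (-0.93 to -0.21). The iron-sulfur cluster gene iba57 and the arginyltransferase gene ate1 both had -0.62 (-1.07 to -0.17 and -1.08 to -0.16). For itprip it was -0.62 (-1.03 to -0.21), for the homeobox gene hoxa13 -0.59 (-1.01 to -0.16), for the sulfotransferase gene hs6st2 -0.47 (-0.79 to -0.15) and for the protocadherin gene pcdh19 -0.44 (-0.79 to -0.09). The limma adjusted p was 1.00 for each. With normexp background correction, run on median signals so that the correction and the signal both differed, the median of all probes was 0.23. There maob stood at 0.37 and vwc2 at 0.55, and others moved towards 0: thsd1 to -0.028, pcdh19 to -0.098, hs6st2 to -0.13, itprip to -0.21, tacc1 to -0.23, iba57 to -0.27 and ate1 to -0.29.

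**Figure D2:**
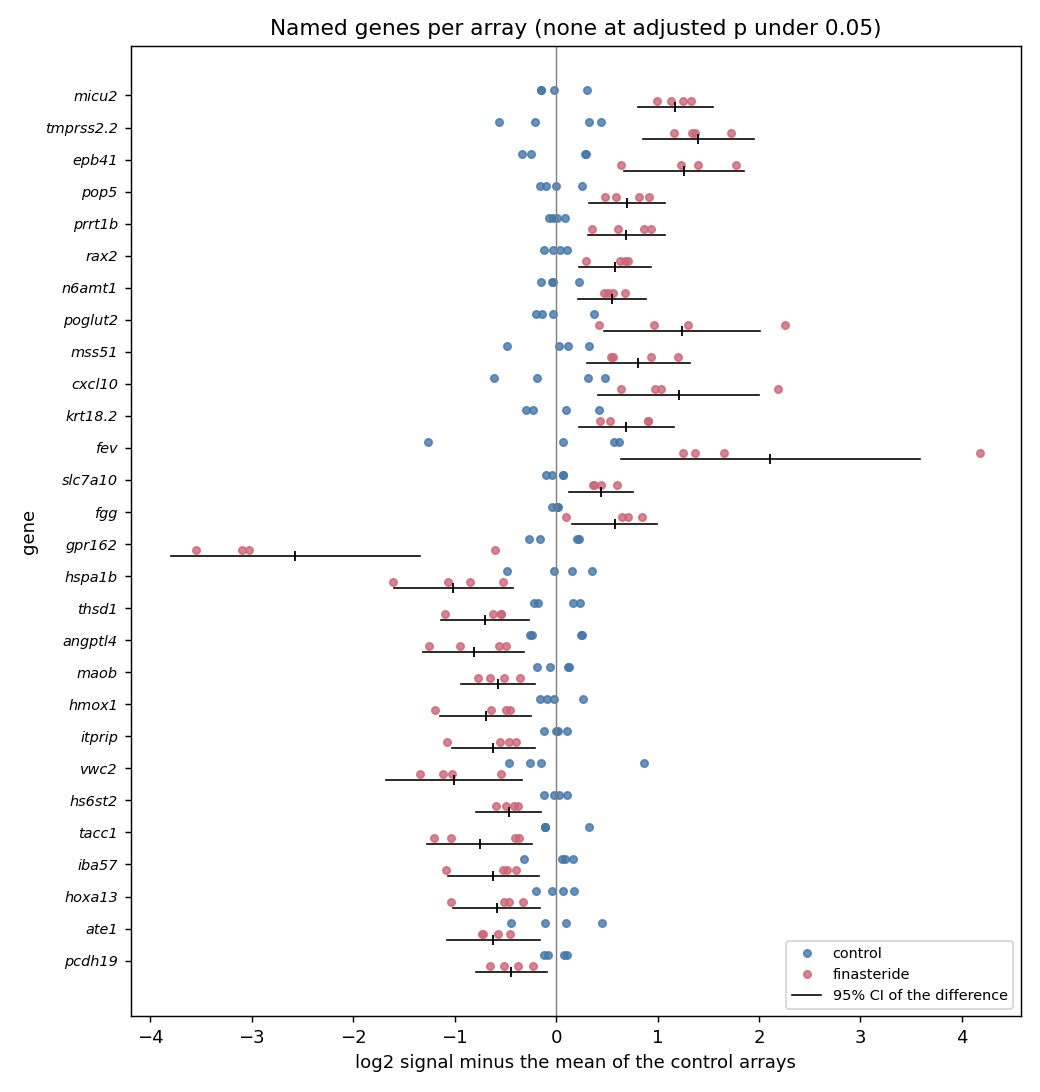
Log2 signal of each array minus the mean of the control arrays (horizontal) for the named genes (vertical), with blue points for controls, red points for finasteride and a black line for the 95% interval of the difference. No gene passed the adjusted p. The 4 finasteride points of each gene lie outside its control points because the genes were chosen for no overlap. For gpr162, finasteride 4 lies closer to the controls than the other finasteride arrays.

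Among probes without a gene name, GT_EA519_mRNA_specific_016719 had the lowest p, with a log2 fold change of 3.03 (2.19 to 3.87, limma adjusted p = 0.191). In the other direction GT_EA519_mRNA_specific_003317 had -1.41 (-1.81 to -1.01, adjusted p = 0.191). Both were well above background on all arrays.

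Steroid metabolism was examined because finasteride blocks a step of it. Of the 31 genes fixed for steroid synthesis 9 were named on a probe and 8 were tested, so most were not assessed. Of the 8 genes tested, 4 had higher and 4 lower values, and none passed over all probes or adjusted over the list alone. The electron carrier gene fdx1 had a log2 fold change of 0.39 (-0.25 to 1.02), the steroid 21-hydroxylase gene cyp21a2.1 -0.37 (-1.02 to 0.27), the electron donor gene por -0.19 (-0.57 to 0.19) and the cholesterol transport gene star -0.33 (-0.996 to 0.34). The list's median was -0.07 (camera adjusted p = 0.892), and 0.30 within slide 1, -0.18 within slide 2, 0.31 with normexp and 0.069 without finasteride 2. Within slide 1 star stood at 0.27, and with normexp cyp21a2.1 stood at 0.72. With 1 array left out, star ran from -0.61 without control 2 to -0.21 without control 3, and fdx1 from 0.18 without finasteride 1 to 0.61 without finasteride 2. For cyp21a2.1 it was -0.57 without finasteride 3 to -0.20 without control 4, and for por -0.30 without finasteride 2 to -0.11 without finasteride 1. Of 7 genes matched to the steroid receptor and coregulator list 4 had higher values. Among them hes5.1 was matched only through an older symbol and may not belong to it, and without hes5.1 3 of 6 had higher values. In this list nr3c2, the mineralocorticoid receptor, stood at 0.29 (-0.04 to 0.63) and pgrmc2 at -0.35 (-0.92 to 0.23, and 0.49 with normexp). Of 8 cholesterol synthesis genes 6 had lower values, with ldlr at -0.28 (-0.85 to 0.29), from -0.48 without control 3 to -0.12 without control 2. Their median was -0.17 (camera adjusted p = 0.767), but 0.019 without finasteride 1. With normexp it was 0.18, which lay below the median of all probes there (0.23). None of these genes passed over all probes or adjusted over the list alone.

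Stress and signalling genes were tested the same way. Of 11 immediate early genes, which respond first to stimulation, 9 had lower values, with fosl1 at -0.48 (-1.17 to 0.20), atf3 at -0.38 (-0.82 to 0.05, and 0.17 with normexp) and junb at -0.38 (-1.02 to 0.25), and 0 passed over all probes or adjusted over the list alone. Their median was -0.18, with the lowest camera adjusted p of any list (0.573, and adjusted p = 0.940 with an estimated correlation). It was -0.23 within slide 1, -0.04 within slide 2 and -0.29 without control 3. With normexp it turned positive, at 0.11, but stayed below the median of all probes there (0.23), as did atf3. With 1 array left out, fosl1 ran from -0.68 without finasteride 3 to -0.19 without finasteride 2, and junb from -0.59 to -0.22 without the same arrays. Without finasteride 1 the list passed in camera, with a median of -0.22 (adjusted p = 0.0287, and adjusted p = 0.905 with an estimated correlation). Of 10 heat shock and unfolded protein genes 6 had lower values, and 1, hspa1b, passed when adjusted over the list alone (adjusted p = 0.0331). Of 4 oxidative stress and hypoxia genes, too few for a set test, hmox1 passed when adjusted over the list alone (adjusted p = 0.0254). Neither passed over all probes. Of 6 gonadotropin and growth factor genes igf1, a growth factor, stood at -0.62 (-1.18 to -0.07), with normexp at 0.66, and none passed over the list alone. Of 15 inflammation and interferon genes 8 had higher values, of 9 xenobiotic metabolism genes 3, with cyp2a6.1 at 1.18 (0.20 to 2.16, and 0.78 without control 4), of 14 cell cycle genes 8, with birc5 at 0.53 (0.05 to 1.01, and 0.99 with normexp) and orc1 at -0.36 (-0.71 to -0.01, and -0.11 with normexp), and of 10 apoptosis genes 3. None of these passed over all probes or adjusted over the list alone. The probe of cyp2a6.1 was well above background on 1 control array and 3 finasteride arrays, so its fold rests on dim control signal.

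Markers of the cell types of the testis and of neighbouring tissues did not pass as sets. Most genes of these lists could not be assessed. From 59 genes fixed for spermatid and flagellum 8 were tested, from 23 for Sertoli cells 5 and from 18 for Leydig cells 5. Spermatid and flagellum genes had higher values for 7 of 8, with spata6 at 1.00 (-0.10 to 2.11) and at 0.40 without finasteride 3, 1.75 within slide 1 and 0.26 within slide 2, and camera gave an adjusted p of 0.767. Of the 5 Sertoli cell genes 2 had higher values, with krt18.2 past the threshold when adjusted over the list alone (adjusted p = 0.0405), and of the 5 Leydig cell genes 3 did. Of the 5 erythrocyte genes 2 had higher values, with epb41, read from an xhyb probe, past the threshold when adjusted over the list alone (adjusted p = 0.00397). Higher values were found for 5 of 6 leukocyte genes, with cd74 at 0.47 (-0.05 to 0.99, 0.31 without control 2 and 1.00 with normexp), 1 of 5 endothelium genes, which was sox17b.2 at 0.53 (0.04 to 1.03), matched only through an older symbol (0 of 4 without it), 2 of 9 liver genes and 4 of 8 kidney genes, with slc12a3 at -0.74 (-1.35 to -0.13), which was -0.014 with normexp. Spermatogonia (2 of 4 higher), meiosis (1 of 4), peritubular and smooth muscle (2 of 2), fat body (1 of 2) and skeletal muscle (3 of 4) had too few tested genes for a set test. The probe of cd74 was well above background on 1 control array and 3 finasteride arrays. No member of any list passed over all probes.

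Lists of cell machinery and matrix completed the 22 tested as sets. Of 16 collagen and matrix genes 12 had higher values, with a median of 0.14 (camera adjusted p = 0.767), which was -0.016 without finasteride 2. Higher values were found for 3 of 6 oxidative phosphorylation genes, 4 of 6 proteasome genes and 7 of 10 chromatin and DNA methylation genes. Too few for a set test were the ribosome list, with 2 of 3 higher, and the thyroid hormone axis list, with 1 of 3 higher. In the ribosome list mrpl24, a mitochondrial ribosomal protein gene, was matched only through an older symbol, and without it 1 of 2 was higher. No list passed with camera (lowest adjusted p = 0.573), with an estimated correlation (0.940) or with fry (0.787), and with slide as a block none passed either. At an unadjusted p under 0.05, 1 list was found.

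**Figure D3:**
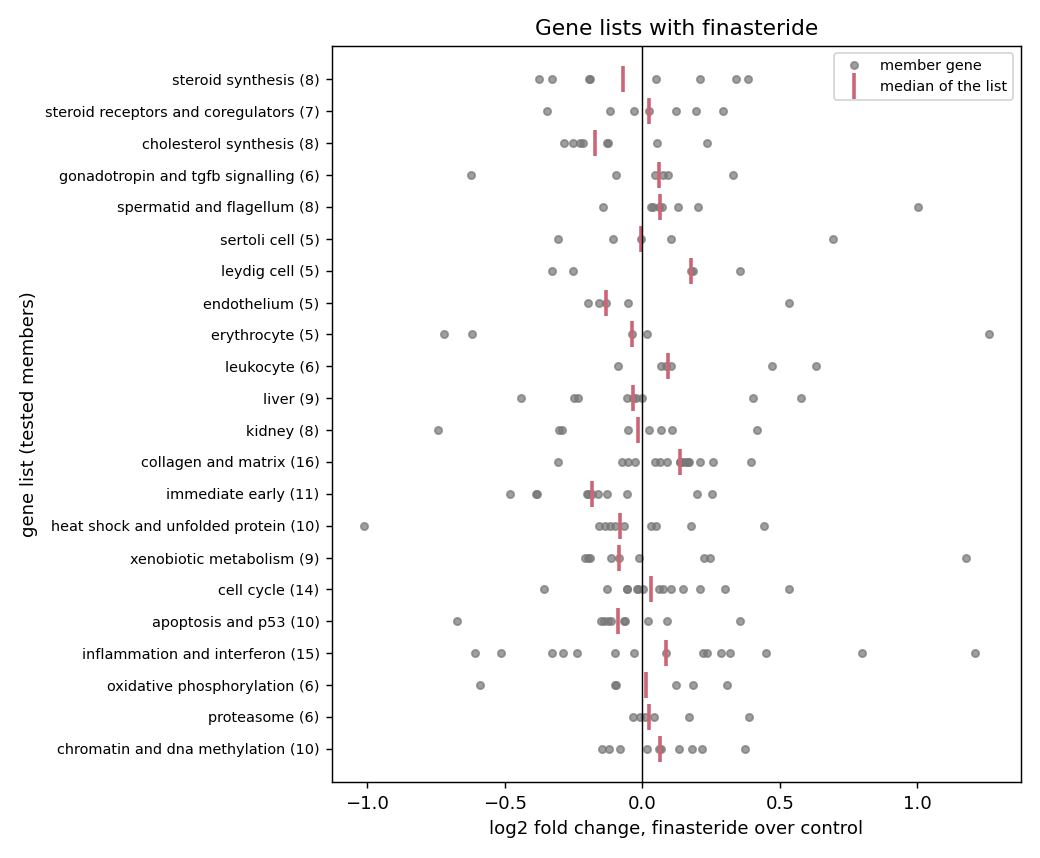
Log2 fold change of finasteride over control (horizontal) for the members of each gene list tested as a set (vertical), with the number of tested members in brackets, a grey point per gene and a red bar at the median. Medians lie between -0.18 and 0.18, and no list passed the set test.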

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

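Of 138 groups of 4 values tested for a sample far from the others, 6 held one, where chance gives about 1 in 20 (6.9 here). For fev, finasteride 2 stood at -2.56, with the other finasteride arrays between -5.49 and -5.09. For thsd1, finasteride 1 stood at -2.66 against -2.18 to -2.11. For tacc1, control 2 stood at -0.95 against -1.39 to -1.38, and for star it stood at -1.15 against -0.12 to 0.05. For fgg, control 4 stood at -0.59 against -0.54 to -0.53, and for spata6, control 1 stood at -2.60 against -2.54 to -2.53.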

How the results depend on the processing

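The restriction to probes named specific, the averaging of repeated transcripts, the first component as a covariate, lists without members matched through older symbols and the values of genes and lists within a slide were chosen after seeing the data. Counts of probes stayed at 0 and 0 under other backgrounds, normalizations, filters, blocks, weights and probe averages. The exceptions were 1 higher within slide 2 and, with 1 array left out, 0 to 2 higher and 0 to 6 lower. The cause of these was not tested. Without adjustment, 391 higher and 266 lower had a limma p under 0.05 and a fold of at least 1.5. They are part of the 1025 probes at that p, fewer than the 1282.6 drawn by chance. Lists past the threshold numbered 0, also among the 21 left without members matched only through an older symbol, and 0 to 1 with 1 array left out.

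With the replicate number as a block, 0 probes and 0 lists passed, and 0 probes with slide added. Deviations of same-numbered arrays correlated at 0.30, 0.36, -0.06 and -0.03, so the numbers were not taken to pair samples. Numbers 1 and 2 correlated best with their own number and 3 and 4 did not.

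With normexp on median signals, where the median of all probes was 0.23, the sign turned for the medians of immediate early (0.11), steroid synthesis (0.31) and cholesterol synthesis genes (0.18), and for maob (0.37), vwc2 (0.55), cyp21a2.1 (0.72), pgrmc2 (0.49), igf1 (0.66) and atf3 (0.17). Within slide 1 it turned for steroid synthesis (0.30) and star (0.27). With 1 array left out it turned for steroid synthesis (0.019 without control 3, 0.069 without finasteride 2, lowest -0.17 without finasteride 3), cholesterol synthesis (0.019 without finasteride 1, lowest -0.23 without finasteride 2) and collagen and matrix genes (-0.016 without finasteride 2). None of these values was past a threshold, and the cause was not tested. Another 636 values of named genes kept their sign and stayed short of the threshold, and gpr162 passed it without finasteride 4 (-3.23). Dim probes limit what can be seen, since 25652 of 32899 were tested.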

Other observations

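The tests of a shared target, of slide position, of treatment as the cause of separate levels and of dim probes were chosen only after the result was seen.

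Over the 35 splits of the arrays into 4 and 4, all 35 gave at least the 0 probes of the real split at the threshold, as any split must, so this count decides nothing, and the highest other gave 42. At an unadjusted p under 0.05, 20 of the 35 splits gave at least the 1025 probes of the real split, the highest other 3406, so chance cannot be excluded. The highest split set control 1, control 3, finasteride 1 and finasteride 4 against the rest. It may follow a structure of the samples other than treatment, but its count was not tested against the highest that chance gives over as many splits. The split by slide gave 517.

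A block of 11 probes, all named xhyb and none with a gene symbol, stood at -3.84 ± 0.53 on control arrays and -5.37 ± 0.47 on finasteride arrays (SD, n = 4 each), with a median log2 fold change of -1.51, and no probe of it passed the threshold. Noise at low signal stays open: 1369 other probes at that level had a median of 0.052, but the block was chosen for correlating above 0.95 with an xhyb probe lower with finasteride. No single array made it, since the median was -1.31 without finasteride 4, the array whose removal weakened it most. The probes' design numbers lay closer together than those of random sets of xhyb probes (share 1e-04, the smallest 10000 sets can give), so 1 shared target read by several probes is a candidate explanation. An effect of finasteride and the position of the arrays on the slide cannot be told apart for it.

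Of 25596 probes, 37 split the arrays into separate levels more than 3 log2 apart with at least 2 arrays on each side. Of these 13 were low in control 2, control 4 and finasteride 2 and 9 in control 2 and control 4, and leo1 stood at -7.82, -7.56 and -7.32 there and between -1.99 and -1.16 elsewhere. A spot artefact is argued against for the 13 probes with 2 spots, since the spots of all of them (100%) differed by less than 0.5 of the gap. Probes with 1 spot could not be tested this way. By treatment 0 of the 37 probes (0%) split exactly. The probes low in control 2 and control 4 parted controls from controls, which argues against treatment as the sole cause for those. Some others had only finasteride arrays on 1 side, such as 2 probes low in finasteride 1 and finasteride 3. For these a response in part of the finasteride arrays stays open. Slide position cannot be told apart for the 11 probes (29.7%) that split by 1 position, while the other 26 part arrays of the same position. A sequence variant under 1 probe stays open: the only other probes of the same gene, the 2 of fryl, shared the split (100% of 2 cases). These cases are 1 pair counted from each side, and both probes were themselves among the 37, so they are too few to decide. A difference in genotype between the animals may give such levels and was not tested.

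Finasteride arrays spread more widely than controls, with a median SD of 0.35 against 0.23, a ratio of 1.53. Chance cannot be excluded: 4 of the 70 labellings gave a ratio as far from 1, among them the real one and its mirror image. The highest ratio of the others was 1.79. Noise of dim probes is argued against by a ratio of 1.76 among the brightest 25% of probes, and without any 1 finasteride array the ratio stayed at 1.28 or more, lowest without finasteride 1.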
